A study of Homo sapiens with 25 samples.

How the data were processed

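The series holds 25 ATAC-seq libraries of GM21 human skin fibroblasts transduced with an empty vector (8 libraries, days 8, 32 and 56) or with oncogenic RAS (17 libraries, days 8, 14, 18, 23, 32, 45 and 56). Per the labels' protocols, nuclei were tagmented with Tn5 and the libraries amplified by PCR. Group and day were taken from the sample titles, and replicate numbers from the same titles.

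Per the submitters' processing notes, the tools used were Trimmomatic, Bowtie2, SAMtools, MACS2, deepTools and MultiQC on the build hg19, and versions, order and settings are not given in the sources used here. Whether reads were shifted for the Tn5 insertion offset is not given in the sources used here either; a shift of a few bases is far below the width of the windows used. Each deposited file is a MACS2 peak list of 1 library, so peaks were called per library and not on pooled samples. The lowest −log10 p-value in a list lay between 3.0 and 3.05, so the lists reach down to a p of 0.001. For each peak the authors' lists give the fold enrichment of the summit over the local background (a linear ratio), the deposited −log10 p-value and −log10 q-value, and a deposited score. That score was 10 times the −log10 p-value in all but 110 of 3383500 lines. All these values are the authors' own, relative to the background of the same library, and were used only to rank or filter peaks within a list.

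The deposited lists give no read totals. An index of depth was recovered by solving, for 1500 peaks per library with a −log10 p under 30, the Poisson background that gives both the deposited fold and the deposited p-value. Between 99.93 and 100% of those peaks were solved within 0.002 per library, and between 1.2 and 3.07% when fold and p were paired at random. The most frequent background value of a library, divided by the width of its narrowest peak, ran from 3.5 to 29.32 tags per kb (median 13.07). The lists held 75598 to 177665 distinct intervals on chromosomes 1 to 22 and X (median 137006), and other sequences were left out. A longer list can come from a deeper library, and a weak site missing from a list may be undetected at that depth and need not be closed.

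Peak names inside the lists carry names of processing batches, which the labels do not give. These formed 3 series, of 9, 9 and 7 libraries. The series of 7, called the separate run here, has names that record removal of duplicates and of blacklisted regions. The names do not say whether the sequencing differed or only the processing. It holds replicates 2 and 4 of empty vector day 8 and of RAS day 23, replicate 2 of RAS day 8 and both replicates of RAS day 18, and no RAS library of days 32 to 56. In 4 lists the names give another day than the label: replicate 1 of empty vector day 32 (day 38), replicates 2 and 4 of RAS day 23 (day 22) and replicate 2 of RAS day 8 (day 10). The labels were kept. No replicate pair shared more than 200 identical intervals (0.127% of the shorter list), so none was treated as a library deposited more than once.

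To compare lists of equal length, each was shortened to its 75598 strongest intervals by −log10 p, the length of the shortest list. Calls are therefore ranks within a library. A site pushed below the cut by stronger ones counts as not called, so a lost window need not have closed. Windows of 501 bp were placed around summits, best rank first and without overlap, and 136113 called in at least 2 libraries were kept. A library called a window when one of its intervals overlapped it by at least 1 bp. A window is called gained or lost where the number of libraries that call it differed between groups by Fisher's exact test, two-sided, at a Benjamini-Hochberg adjusted p of 0.05 or less, over windows whose margins allow a p of 0.01 or less. Windows were tested in 5 comparisons: all RAS, RAS days 8 to 14, days 18 to 23 and days 32 to 56 against the empty vector, and RAS days 32 to 56 against days 8 to 23. Day-matched groups of 2 to 4 libraries were compared by counting windows called in every library of one group and none of the other. Means are given with the SD over libraries, and comparisons of 1 value per library used exact permutation tests, two-sided. For overlaps between comparisons that share controls, unchanged groups were simulated 20 times against the same controls, in which no window passed, and the controls were also divided between the comparisons. The overlap of independent lists was counted over windows tested in both comparisons, or, for lists of complete separation, over windows not called in every library. The latter include windows called in too few or too many libraries to be in both lists, which makes that count too low.

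The regions named were fixed by a rule before the data were examined: per comparison and direction, the 5 bins of 500 kb with the most gained or lost windows, and the 5 windows with the smallest p and then the best median rank, of which the text gives some. Gene lists and sequence motifs had also been fixed, for use with a genome and annotation of the build of the lists. The only reference used here was a gene table of another build, GRCh38, so tests of gene lists and motifs, and names of genes, were left out.

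The procedure was tested on simulated data: 2000 of 136113 windows changed from a call rate of 5% to 95%, or from 20% to 80%. For RAS days 8 to 14 it recovered 51.1% and 5.2% of them, for days 18 to 23 47.6% and 4.8%, for days 32 to 56 48.8% and 4.8%, for late against early RAS 79.4% and 12.0%, and for all RAS 97.6% and 37.4%. False calls made up at most 1.64%, and with no change there were 0 calls. The simulated libraries were drawn independently at the call rate of each window over all libraries, without differences in depth or series. These rates therefore do not cover false calls from such differences. Partial changes are therefore mostly missed at these group sizes.

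Alternatives fixed before the data were examined were lists of 37799 intervals, every interval as deposited, ranking by fold, only intervals with a −log10 q of 5 or more, an overlap of at least 251 bp, a summit inside the window, windows called in at least 4 libraries, no filter on attainable p, the replicate number as a block, the even-numbered controls choosing the windows, and each library left out in turn. Alternatives chosen after seeing the data were the 3 series as a block, leaving out the separate run, leaving out the 4 libraries named for another day, the empty vector of days 32 and 56 alone, each of RAS days 18 and 23 left out, and the comparison of late list lengths. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.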

Results

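Chromatin accessibility was measured by ATAC-seq (transposase Tn5 cuts and tags DNA that is not wrapped tightly in chromatin) in GM21 cells, a culture of human skin fibroblasts. The cells had been transduced with oncogenic RAS, a mutated growth signal that drives normal fibroblasts into senescence, a lasting arrest of division, or with an empty vector. The series followed cells into and out of that arrest. Its 25 libraries were 4, 2 and 2 of empty vector at days 8, 32 and 56, and 3, 2, 2, 4, 2, 2 and 2 of RAS at days 8, 14, 18, 23, 32, 45 and 56 after transduction. RAS libraries were compared in 3 periods fixed before the data were examined, days 8 to 14 (n = 5), days 18 to 23 (n = 6) and days 32 to 56 (n = 6), each against all 8 empty vector libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Regions are given as chromosome, start and end in hg19, and gene annotation of that build was not used here.

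The deposited lists of accessible intervals were longer on average in RAS than in empty vector libraries of the same age. On day 8 the lists held 141696 ± 5995 intervals in RAS (SD, n = 3) and 100426 ± 25097 in the empty vector (SD, n = 4), a ratio of 1.41. The median interval was 399 ± 64.7 bp wide in RAS and 524 ± 51.4 bp in the empty vector. Both differences gave a two-sided exact permutation p of 0.0571, the smallest that 3 against 4 libraries allow, and an adjusted p of 0.114. At days 32 to 56, a comparison added after the lists were seen, RAS held 151159 ± 9864 intervals (SD, n = 6) and the empty vector of days 32 and 56 held 120680 ± 9105 (SD, n = 4), a ratio of 1.25. That difference had a two-sided exact permutation p of 0.00952, the smallest that 6 against 4 libraries allow, and an adjusted p of 0.0381. The density of background tags recovered from the lists, used as an index of depth, had the same mean in both arms on day 8 (8.45 ± 1.68 per kb in RAS, SD, n = 3, and 8.45 ± 6.09 in the empty vector, SD, n = 4). Single libraries ran from 6.84 to 10.2 in RAS and from 3.5 to 16.87 in the empty vector, so depth was not matched. It was 18.8 ± 5.87 per kb in late RAS (n = 6) and 13.5 ± 4.24 in late empty vector (n = 4), with an exact permutation p of 0.171.

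Over all libraries the lists ran from 75598 to 177665 intervals and the background from 3.5 to 29.32 tags per kb. Because of this spread, every list was shortened to its 75598 strongest intervals before regions were compared. These gave 136113 windows around summits, called in at least 2 libraries, of which 32230 (23.68%) were called in all 25.

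At days 8 to 14 RAS cells had gained 6078 windows and lost 4427 relative to the empty vector, or 14.34% and 10.44% of the 42395 that could be tested (5 against 8 libraries). The window at chromosome 11, 36770289 to 36770789, was called in 5 of 5 RAS libraries and 0 of 8 empty vector libraries, as were those at chromosome 13, 109643778 to 109644278, and chromosome 2, 175914357 to 175914857. The window at chromosome 12, 128293783 to 128294283, was called in all 8 empty vector libraries and in none of the 5 RAS libraries, as were chromosome 5, 131007894 to 131008394, and chromosome 9, 125831390 to 125831890. Gains were dense in chromosome 12, 107500001 to 108000000, where 8 of 21 tested windows were gained and none lost, and in chromosome 20, 14500001 to 15000000 and 31000001 to 31500000, with 8 of 13 gained and none lost in each. In chromosome 8, 58000001 to 58500000, 8 of 15 were gained and 1 lost. Over the whole of chromosome 20, 205 windows were gained and 49 lost. Losses were dense in chromosome 12, 66000001 to 66500000 (10 of 23 tested windows, with 2 gained), chromosome 2, 223500001 to 224000000 (9 of 25, with 1 gained), and chromosome 12, 90000001 to 90500000 (8 of 19, with 0 gained).

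Each such window passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment (p = 0.000777, adjusted p = 0.00808 for 5 of 5 against 0 of 8). Of the windows that passed, 2485 gained and 1591 lost separated the arms completely. With every interval as deposited, the split moved to 12186 gained and 1893 lost, and with intervals of a −log10 q of 5 or more to 11004 and 1606. The number of losses thus depends on cutting the lists to equal length, where a loss can be a fall in rank. With lists of 37799 intervals, no filter on attainable p, the series as a block, the 4 libraries named for another day left out, the separate run (7 libraries set apart by the names of their peaks) left out, or any 1 of the 13 libraries left out, 2485 to 3342 windows were gained and 1591 to 2245 lost.

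On day 8 alone, where 3 RAS libraries met 4 empty vector libraries of the same age, 5585 windows were called in every RAS library and in no empty vector library, and 4413 the other way round. With every interval as deposited these counts were 10559 and 1845, at a −log10 q of 5 or more 9545 and 1547, and with lists of 37799 intervals 3055 and 2185. No adjusted test was made at this size. The same count on day 32 was 3046 in RAS only and 2723 in the empty vector only. On day 56 it was 2616 and 3509, each with 2 libraries against 2 (12961 and 1683, and 14298 and 2172, with every interval as deposited). A −log10 q of 5 or more gave 11348 and 956 on day 32 and 13816 and 1342 on day 56. Lists of 37799 intervals gave 1299 and 1195, and 1385 and 1798. With any 1 library left out, the counts were 5917 to 7643 and 5962 to 7166 on day 32, and 5071 to 9148 and 6757 to 8399 on day 56. For these days, another division of the same 4 libraries into pairs gave more windows than RAS against empty vector did, 7124 against 5769 on day 32 and 6969 against 6125 on day 56.

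At days 18 to 23 RAS cells had gained 3828 windows and lost 3223 of the 30244 tested (6 against 8 libraries). The window at chromosome 1, 91546126 to 91546626, was called in 6 of 6 RAS libraries and 0 of 8 empty vector libraries, as was chromosome 17, 53751433 to 53751933. The window at chromosome 18, 71813939 to 71814439, was called in 0 of 6 RAS libraries of these days and in all 8 empty vector libraries. In chromosome 1, 58500001 to 59000000, 7 of 11 tested windows were gained and 2 lost. The 7 gained were called at 88.1% ± 29.2 in RAS of these days (SD over libraries, n = 6), at 3.6% ± 6.6 in the empty vector (n = 8) and at 14.3% ± 12.8 in RAS of days 32 to 56 (n = 6). In chromosome 12, 90000001 to 90500000, where 1 window was gained, the 9 lost windows stood at 3.7% ± 5.7 in RAS (n = 6) against 90.3% ± 11 in the empty vector (n = 8).

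A window called in 6 of 6 against 0 of 8 libraries had p = 0.000333 by Fisher's exact test and an adjusted p of 0.0071. Of the gains, 2093 were also gains of days 8 to 14, where independent lists would share 291.7, and of the losses 1736 were shared, where independent lists would share 264.6. Both comparisons used the same 8 controls, and unchanged groups simulated against them passed no window, so they give no value for the overlap. When each comparison used its own 4 controls, 559 windows were gained with complete separation in both, of 1451 and 1408 at days 18 to 23 under the 2 assignments of controls (46.68 and 47.18 for independent lists). For losses it was 416, of 1276 and 1335 (35.02 and 39.31). These are by logic the same windows that separate completely in both comparisons with all 8 controls, of 866 gained and 552 lost at days 18 to 23. Dividing the controls therefore cannot change the number shared. Counts for independent lists of complete separation are too low, as they include windows that could not be in both lists. The separate run held 4 of the 6 RAS libraries of these days and 2 of the 8 empty vector libraries. Without it, 2 RAS libraries against 6 allow no p under 0.0357. Within that run 9489 windows were called in all RAS libraries and no empty vector library, outside it 1850, and 866 were in both lists (169.0 for independent lists). For losses the counts were 8303, 1475 and 552 (117.9 for independent lists). With every interval as deposited, 6864 windows were gained and 832 lost, and at a −log10 q of 5 or more 6488 and 537. Lists of 37799 intervals, no filter on attainable p, the series as a block, leaving out day 18, or leaving out the libraries named for another day gave 866 to 1916 gained and 552 to 1437 lost.

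At days 32 to 56, 120 windows were gained and 94 lost of the 24187 tested (6 against 8 libraries), and in every one the arms separated completely. The gained windows included chromosome 8, 143316344 to 143316844, chromosome 18, 29666802 to 29667302, and chromosome 1, 233365768 to 233366268, each also called in all 11 RAS libraries of days 8 to 23 and in no empty vector library. The lost windows included chromosome 13, 110106812 to 110107312, and chromosome 11, 122213980 to 122214480, called in all 8 empty vector libraries and in none of the 17 RAS libraries. Chromosome 4, 75000001 to 75500000, held 3 gained windows, which were called at 73.3% ± 27.9 at days 8 to 14 (n = 5) and 27.8% ± 25.1 at days 18 to 23 (n = 6). The window at chromosome 11, 115150852 to 115151352, was lost at days 32 to 56 although 4 of the 5 libraries of days 8 to 14 called it.

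These windows had p = 0.000333 by Fisher's exact test, two-sided, and an adjusted p of 0.0376, and 1825 gained and 1895 lost windows had an unadjusted p under 0.05. No window passed when any 1 of the 6 RAS libraries, replicate 3 of empty vector day 8 or replicate 2 of empty vector day 32 was left out (1542 to 2093 gained and 1467 to 1862 lost at an unadjusted p under 0.05). None passed with lists of 37799 intervals (787 and 774 at an unadjusted p under 0.05), with no filter on attainable p (2343 and 2241), or against the empty vector of days 32 and 56 alone (266 and 366). Every interval as deposited gave 513 gained and 4 lost. Leaving out replicate 2 of empty vector day 56 gave 194 gained windows, and an overlap with most of the window gave 74. A −log10 q of 5 or more gave 654 gained and 2 lost, and the series as a block or leaving out the separate run gave 180 lost.

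The windows that set late RAS cells apart were compared with those that had changed early. Of the 120 gained windows 90 (75%) were gains of days 8 to 14, where independent lists would share 3.2, and of the 94 lost windows 83 (88.3%) were losses of days 8 to 14, where independent lists would share 3.1. Both comparisons used the same 8 controls, which raises such overlaps and rules out a change in the opposite direction. As the late windows separated the arms completely, any of them that could be tested at days 8 to 14 passed there by construction. The counts for independent lists therefore decide nothing here. The shares that early libraries called are free of this, as those libraries had no part in choosing the windows. For the 94 lost windows that share was 8.94% ± 4.97 at days 8 to 14 (SD, n = 5). The 120 gained windows were called at 78.7% ± 4.27 at days 8 to 14 (SD, n = 5) and 81.7% ± 7.32 at days 18 to 23 (n = 6). Unchanged groups simulated against these controls passed no window, so they give no value for the overlap. By the stricter rule of complete separation in both comparisons, 63 of the 120 gained (52.5%) and 69 of the 94 lost windows (73.4%) were shared. When the early and the late comparison each used their own 4 controls, the same windows were shared, which follows by logic. They were then, for gains, 63 of 422 late ones (14.9%) and 63 of 291 (21.6%) under the 2 assignments of controls, where independent lists would share 13.58 and 9.75. For losses they were 69 of 422 (16.4%) and 69 of 312 (22.1%), where independent lists would share 11.58 and 9.19. These counts for independent lists are too low, as they include windows that could not be in both lists.

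The larger part of the early gains was no longer among the 75598 strongest intervals late. The 6078 windows gained at days 8 to 14 were called at 91.8% ± 2.62 on day 8 (SD, n = 3), 92.7% ± 7.02 on day 14 (n = 2), 83.3% ± 0.22 on day 18 (n = 2) and 50.6% ± 7.35 on day 23 (n = 4). Their share was 27.1% ± 5.9 on day 32 (n = 2), 21.1% ± 13.2 on day 45 (n = 2) and 33.1% ± 21.5 on day 56 (n = 2), with 2.5% ± 2.44 in the empty vector (n = 8). The 4427 lost windows were called at 5.65% ± 3.14 on day 8 (n = 3) and 41.6% ± 7.67 on day 23 (n = 4). Their share was 72.7% ± 5.62 on day 32 (n = 2), 66.7% ± 1.34 on day 45 (n = 2) and 60.0% ± 13.3 on day 56 (n = 2), with 96.0% ± 2.47 in the empty vector (n = 8). Libraries of days 8 and 14 and of the empty vector took part in choosing these windows, so their shares are extreme by choice. Late shares ranged between regions. In chromosome 6, 25000001 to 25500000, the 8 lost windows stood at 87.5% ± 15.8 at days 32 to 56 (n = 6), against 98.4% ± 4.4 in the empty vector (n = 8). In chromosome 12, 66000001 to 66500000, the 10 lost windows stood at 50.0% ± 15.5 at days 32 to 56 (n = 6), against 96.2% ± 5.2 in the empty vector (n = 8). Among early gains, the 8 windows of chromosome 20, 31000001 to 31500000, stood at 14.6% ± 9.4 at days 32 to 56 (n = 6) and the 8 of chromosome 8, 58000001 to 58500000, at 47.9% ± 22.9 (n = 6). The differences between these regions were not tested.

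The remainder was measured against empty vector libraries that had no part in choosing the windows. Of 3342 windows called in all 5 RAS libraries of days 8 to 14 and in none of the 4 odd-numbered empty vector libraries, late RAS libraries called 33.3% ± 15.2 (SD, n = 6) and held-out empty vector libraries 8.6% ± 6.54 (SD, n = 4). The difference was 24.69 percentage points (two-sided exact permutation p = 0.019). Of 2851 windows lost in the same sense, late RAS libraries called 58.7% ± 10.5 (SD, n = 6) and held-out empty vector libraries 80.5% ± 6.34 (SD, n = 4), a difference of −21.81 points (exact permutation p = 0.00952, n = 6 and 4). RAS libraries of days 18 to 23 lay further out, at 70.1% ± 16.9 of the gains and 22.4% ± 15.4 of the losses (exact permutation p = 0.00952 for each, n = 6 and 4). Of the held-out controls 2 were of day 8, 1 of day 32 and 1 of day 56, so age was not matched. For gains the day 56 control called 18.4%, above the lowest late RAS library (15.29%). With even-numbered controls choosing instead, held-out controls of day 8 called 12.56% of the gains on average (n = 2). Those of days 32 and 56 called 10.89 and 8.85% (n = 1 each). Of the chosen gains that a late RAS library did not call, 65.8% ± 11.3 (SD, n = 6) met a weaker interval of its list beyond the 75598 strongest, against 13.04% ± 14.1 in held-out empty vector libraries (SD, n = 4, exact permutation p = 0.00952). Among all other uncalled windows 65.5% and 22.5% did. The excess over these was 0.29 ± 5.83 points in late RAS (SD, n = 6) and −9.49 ± 7.63 in the held-out empty vector (SD, n = 4, exact permutation p = 0.0857). Without the separate run, 2 held-out controls remained and the differences were 20.57 points (exact permutation p = 0.143) and −25.6 points (p = 0.0714, the smallest that 6 against 2 libraries allow). With lists of unequal length the difference for gains rose to 39.6 points (every interval as deposited, exact permutation p = 0.00952, n = 6 and 4) or 43.2 points (−log10 q of 5 or more, p = 0.00952). The difference for losses turned to 5.47 points (every interval as deposited, exact permutation p = 0.533) or 10.7 points (−log10 q of 5 or more, p = 0.343).

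**Figure D1:**
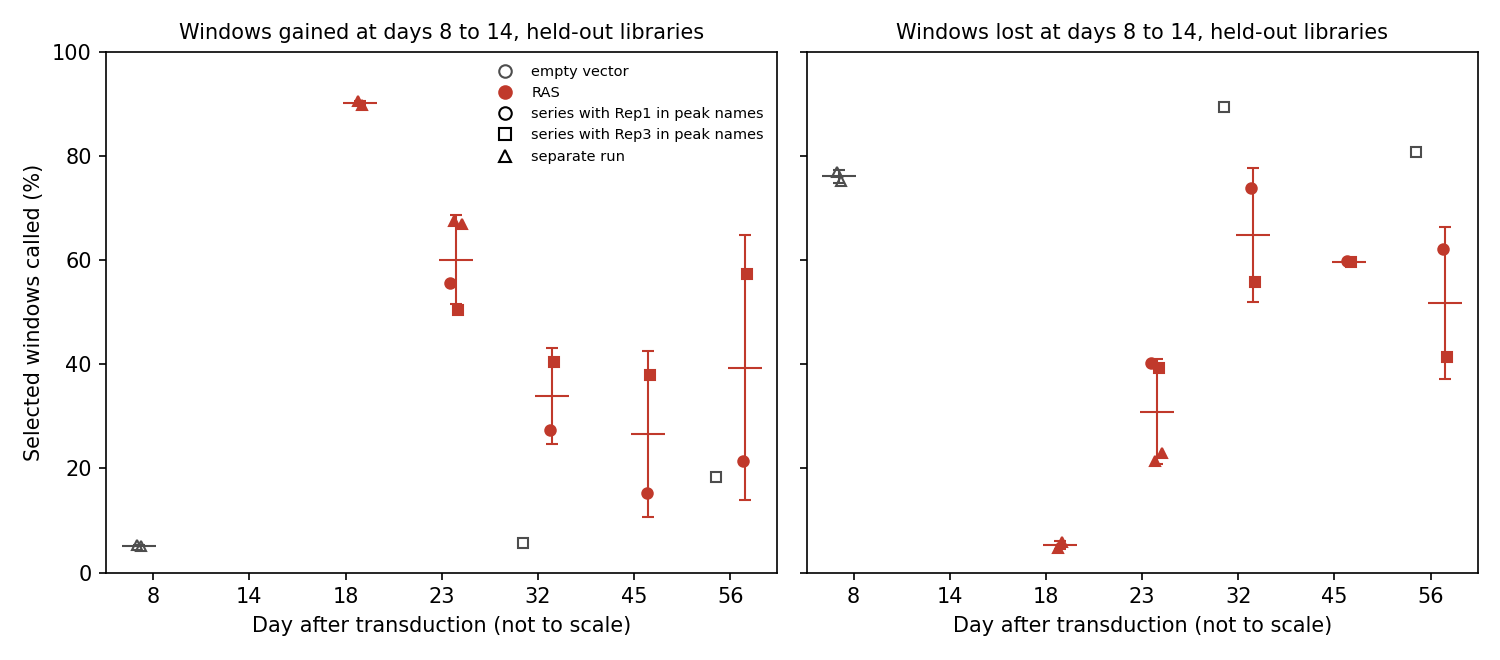
Share in percent of windows gained (left, 3342 windows) or lost (right, 2851 windows) at days 8 to 14 that each library not used to choose them called, by day after transduction. Points are libraries, bars the mean and SD of days with at least 2 libraries, and marker shapes the series read from the peak names. Late RAS libraries lay between 15.29 and 57.33% for gains, and held-out empty vector libraries between 5.09 and 18.4%.

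Set against RAS cells of days 8 to 23, RAS cells of days 32 to 56 had gained 568 windows and lost 537 of the 48411 tested (6 against 11 libraries). The windows at chromosome 3, 179134432 to 179134932, chromosome 10, 81565509 to 81566009, and chromosome 8, 25009375 to 25009875, were called in all 6 late and none of the 11 earlier RAS libraries, and in all 8 empty vector libraries. The window at chromosome 11, 113005276 to 113005776, was called in all 11 earlier RAS libraries and in no late or empty vector library. Chromosome 10, 110500001 to 111000000, held 3 gained windows called at 100% in late RAS (n = 6), 5.6% ± 13.6 at days 18 to 23 (n = 6), 0% at days 8 to 14 (n = 5) and 25% ± 29.5 in the empty vector (n = 8). Of the 537 lost windows 374 (69.6%) were early gains, and of the 568 gained windows 290 (51.1%) were early losses, where independent lists would share 84.9 and 55.8. The 5 RAS libraries of days 8 to 14 are part of both comparisons, which raises this overlap by construction.

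Windows at 6 of 6 against 0 of 11 libraries had p = 8.08e-05 by Fisher's exact test, two-sided, and an adjusted p of 0.0199. Left out singly, replicates 1 and 3 of RAS day 23 gave 932 and 910 gained and 883 and 843 lost windows. Each of 11 others gave 100 to 154 gained and 98 to 168 lost: both replicates of days 18, 32 and 45, replicates 2 and 4 of day 23, replicate 2 of days 8 and 14 and replicate 1 of day 56. Every interval as deposited gave 243 and 60, a −log10 q of 5 or more 256 and 34, and lists of 37799 intervals 35 and 45. An overlap with most of the window gave 300 and 273, and no filter on attainable p gave 0 and 0 (6917 and 6267 at an unadjusted p under 0.05). The series as a block, or leaving out the separate run, gave 171 gained and 199 lost, and leaving out the libraries named for another day gave 153 and 164.

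Over all RAS days 3669 windows were gained and 4072 lost of the 67903 tested (17 against 8 libraries). The windows at chromosome 8, 143316344 to 143316844 and 11858216 to 11858716, chromosome 1, 233365768 to 233366268, chromosome 18, 29666802 to 29667302, and chromosome 12, 107731066 to 107731566, were called in 17 of 17 RAS libraries and 0 of 8 empty vector libraries. Those at chromosome 13, 110106812 to 110107312, chromosome 11, 122213980 to 122214480, chromosome 1, 219471926 to 219472426, chromosome 12, 93178023 to 93178523, and chromosome 3, 173911310 to 173911810, were called in 0 of 17 and 8 of 8. Chromosome 12, 107500001 to 108000000, held 8 gained windows of 36 tested. These were called at 87.5% at days 8 to 14 (n = 5), 97.9% ± 5.1 at days 18 to 23 (n = 6), 89.6% ± 9.4 at days 32 to 56 (n = 6) and 15.6% ± 14.6 in the empty vector (n = 8). Chromosome 6, 129500001 to 130000000, and chromosome 12, 90000001 to 90500000, held 11 lost windows each, of 17 and 26 tested.

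**Figure D2:**
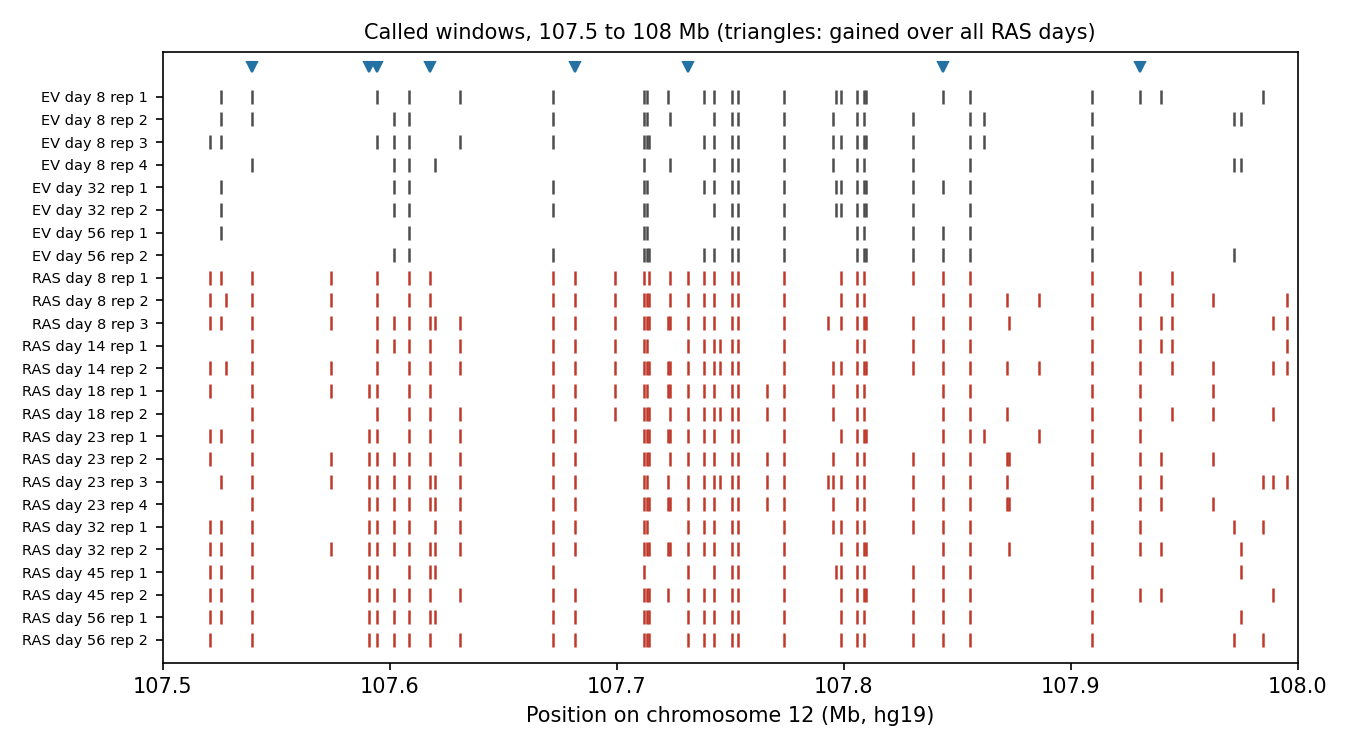
Windows called in each library along chromosome 12, 107500001 to 108000000 (position in Mb, hg19). Each line is a library and each tick a called window, and triangles mark the 8 windows gained over all RAS days; the window at 107731066 to 107731566 is called in all 17 RAS libraries and in no empty vector library.

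A window at 17 of 17 against 0 of 8 libraries had p = 9.25e-07 by Fisher's exact test, two-sided, and an adjusted p of 0.000647, and complete separation was seen for 40 gained and 57 lost windows. The split moved to 9908 gained and 668 lost with every interval as deposited and to 9700 and 446 at a −log10 q of 5 or more. Lists of 37799 intervals gave 1483 and 1359, no filter on attainable p 2363 and 2420, leaving out the separate run 293 and 472, and leaving out the libraries named for another day 1254 and 1249. Left out singly, replicate 3 of empty vector day 8 gave 1520 gained and 1465 lost, replicate 4 of that day 1894 and 2455, and replicate 2 of empty vector day 32 2035 and 2357. Replicate 2 of RAS day 14 left out gave 2402 and 2472, and the replicates of RAS day 18 2409 and 2414 gained and 2444 and 2446 lost. Replicate 2 of empty vector day 8 gave 2160 gained, and the 3 replicates of RAS day 8, replicate 1 of day 14 and replicates 2 and 4 of day 23 gave 2448 to 2548 lost.

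Whole profiles of late RAS libraries lay closer to the empty vector than earlier ones. The mean Jaccard index to the empty vector libraries is the share of windows called in both among those called in either. It was 57.11% ± 2.1 at days 8 to 14 (SD, n = 5), 60.11% ± 4.7 at days 18 to 23 (n = 6) and 68.18% ± 2.65 at days 32 to 56 (n = 6), and 71.25% ± 1.62 among the empty vector libraries themselves (n = 8). Day 18 stood at 54.76% ± 0.28 (n = 2) and day 23 at 62.79% ± 2.87 (n = 4). The difference of late RAS was 11.08 points from days 8 to 14, 8.07 points from days 18 to 23 and −3.07 points from the empty vector. Two-sided exact permutation tests (n = 5 to 8) gave p = 0.00433, 0.00433 and 0.0167, or 0.00866, 0.00866 and 0.0223 adjusted over 4 tests. Days 18 to 23 differed from days 8 to 14 by less than the spread between libraries (exact permutation p = 0.216, n = 6 and 5). Without the separate run the 3 differences were 10.2 points (exact permutation p = 0.00952), 5.08 points (p = 0.143, with 2 libraries left at days 18 to 23) and −3.59 points (p = 0.00866). The tests of late RAS against the empty vector, with p = 0.0167 and 0.00866, are not valid as exact permutation tests. The empty vector libraries were also the reference, so their values depend on each other, and these p-values are only a guide.

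**Figure D3:**
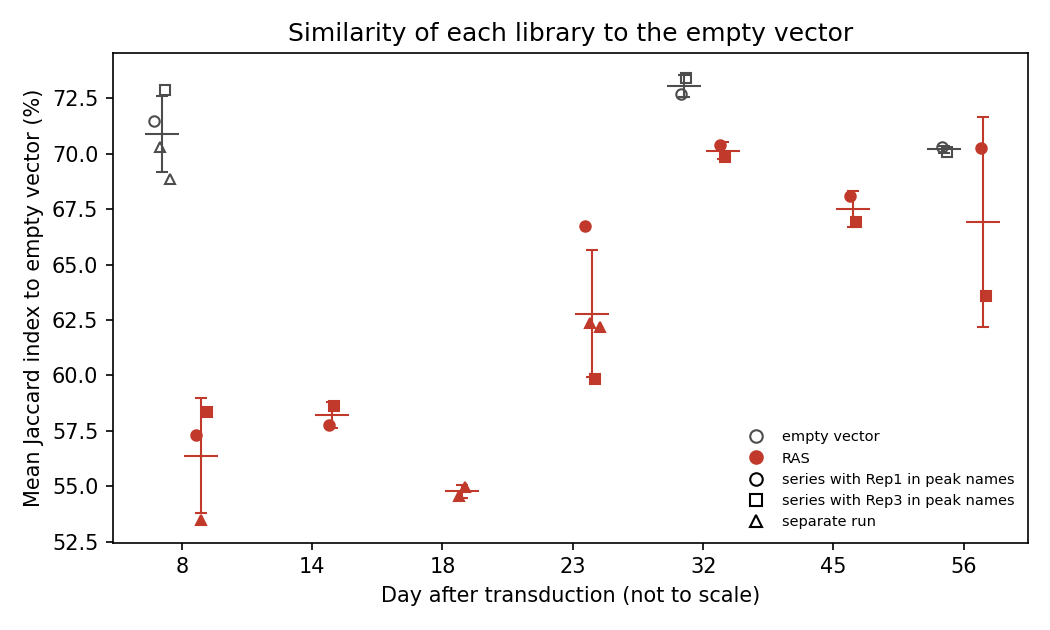
Mean Jaccard index in percent of each library's called windows to those of the empty vector libraries, by day after transduction. Points are libraries, bars the mean and SD per day, colours the arm and shapes the series. Late RAS libraries lie between 63.56 and 70.4%, RAS libraries of days 8 to 14 between 53.46 and 58.62%.

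**Figure D4:**
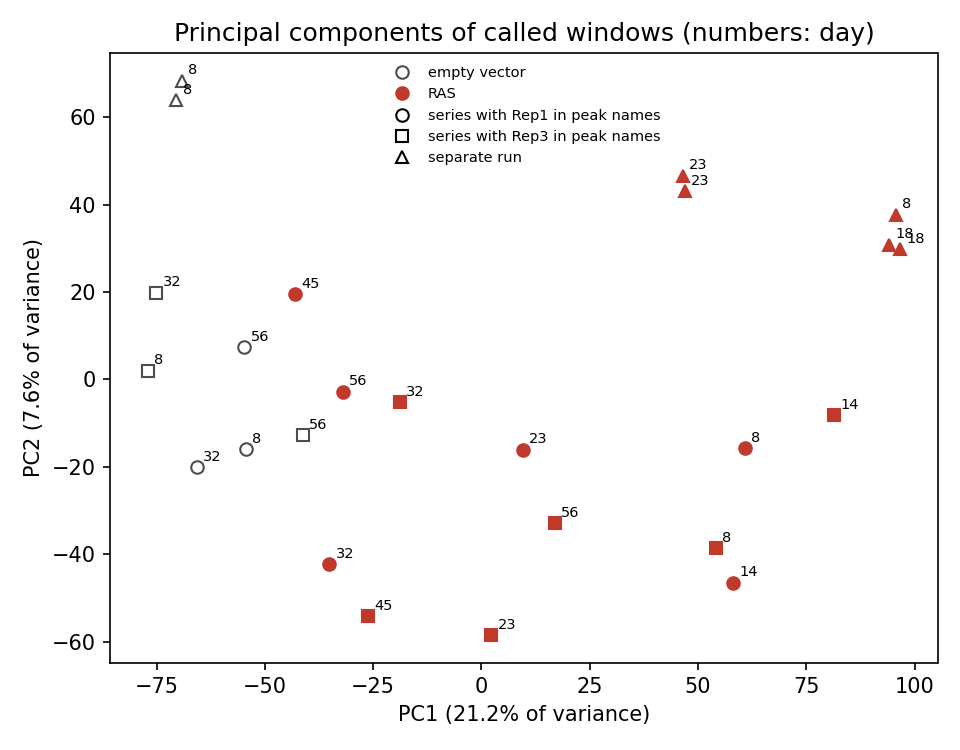
First 2 principal components of the matrix of called windows (component 1, 21.2% of variance, component 2, 7.6%). Points are libraries, numbers the day, colours the arm and shapes the series. RAS libraries of days 8 to 18 lie at the far side of component 1 from the empty vector and most later ones between, while component 2 parts the separate run from other libraries of the same arm and day.

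Time in culture without RAS was followed in the empty vector alone. Between day 8 and days 32 and 56 (4 against 4 libraries), 330 windows were called only late and 268 only on day 8, 598 in all. Of the 35 divisions of these 8 libraries into 4 and 4, another gave more (942). Leaving out any 1 of the 8 libraries gave 439 to 870 windows called only late and 333 to 665 called only on day 8. Every interval as deposited gave 864 and 65, a −log10 q of 5 or more 946 and 34, and lists of 37799 intervals 155 and 161.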

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

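The tests without the separate run for days 8 to 14 and for days 32 to 56, the test of the day 23 libraries, the tests of time in culture and of library depth as the whole cause and the splits of the day 8 libraries were chosen after the result was seen.

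Replicate 2 of RAS day 14 stood apart from the other 4 libraries of days 8 to 14, with 177665 intervals and 29.32 background tags per kb, each the highest of the 5. Replicate 2 of RAS day 8 stood apart in the same group, with the lowest similarity to the empty vector, 53.46%. Replicate 1 of empty vector day 8 called 4.57% of the windows gained at days 8 to 14, where the other 3 libraries of its day called 0.84 to 0.9%. In 36 groups tested for a sample far from the others, 4 such values were found, and chance gives about 1 in 20 groups. The similarity of late RAS libraries to the empty vector differed from that of days 8 to 14 by 11.08 points and from that of days 18 to 23 by 8.07 points, each past a permutation test of the difference.

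For the windows of all RAS days only the real grouping gave as many (7741 in the real grouping, 0 in the highest other, 1 of 100 splits with as many). The same holds for days 8 to 14 (10505, 0 and 1 of 100 splits), for late against early RAS (1105, 0 and 1 of 100 splits) and for day 8 (9998, 3742 and 1 of 35 splits). A chance division is thus unlikely but not excluded, as the splits ignored the series and replicates may be technical. Counts after adjustment fall to 0 in any split with too few small p-values, so the 0s do not show how far apart the groupings lay. At days 8 to 14, 5198 windows passed without the separate run, which decides little, since 4076 of the 10505 separated the arms completely and leaving out libraries cannot undo that. A grouping of the same libraries by library depth gave 0 windows by Fisher's exact test with adjustment, as did every other split drawn, so it decides nothing.

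The first pattern weighed is the set of 214 windows that set RAS of days 32 to 56 apart. Of 100 splits only the real grouping passed any window (214, with 0 in the highest other). This makes a chance division of these libraries less likely but does not exclude it. Adjusted counts are 0 in any split with too few small p-values, and the splits ignored the separate run. Yet no window passed when any 1 of the 6 RAS libraries was left out. On day 32 and on day 56 alone, another division of the 4 libraries gave more windows than the real one (7124 against 5769, and 6969 against 6125). All 214 separated late RAS, which has no library in the separate run, from the 6 empty vector libraries outside it, so the 320 windows that passed without the run were largely fixed beforehand and decide nothing. The tables argue against a shift of a whole chromosome (at most 2.02 times its share of tested windows) and against time in culture as the whole cause, since RAS libraries of days 8 to 14, which had no part in choosing the windows, called 78.7% ± 4.27 of the gained and 8.94% ± 4.97 of the lost ones (SD, n = 5), and against library depth as the whole cause, since the 4 of those libraries with 6.84 to 10.2 tags per kb, under the mean control of 10.97, called 77.3% ± 3.43 and 9.3% ± 5.65 (SD, n = 4); a part for library depth cannot be told apart, as late RAS was deeper (18.8 ± 5.87 against 10.97 ± 5.56 tags per kb, SD, n = 6 and 8) and a grouping by depth gave 0 windows, as did every other split drawn. A part for time in culture stays open from a wider set: of 612 windows called in all late RAS libraries and no day 8 empty vector library, the late empty vector called 45.6% ± 11.4 (SD, n = 4), which is 21.72 points more than the 23.9% ± 10.6 (SD, n = 4) found with the empty vector days exchanged (266 windows), although 2 of the 4 day 8 libraries came from the separate run. Cells remaining in the state of days 8 to 14 cannot be told apart from a lasting change in all cells, since 93.3% of the gained windows were called more often at days 8 to 14 than in the empty vector, which called none of them; either may account for the pattern only as a hypothesis.

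The second pattern is the 7051 windows of RAS days 18 to 23, where the separate run held 4 of 6 RAS and 2 of 8 empty vector libraries. A chance division of these libraries is unlikely (7051 in the real grouping, 0 in the highest other, 1 of 100 splits), but the splits ignored the run. Of the 7051, 1475 gained and 1052 lost windows also passed with the series as a block. Windows that separated the arms within the run and outside it were shared 5.12 times as often as in independent lists for gains and 4.68 times for losses, and 15 and 7 were shared in opposite directions. Both ratios are too high, as the counts for independent lists include windows that could not be in both lists. The bound of 5 set beforehand was passed for gains only, and given this limit the part played by the run cannot be told apart. Whether the run pulled libraries towards the early RAS state cannot be told apart. Its day 23 libraries lay 2.54 points nearer than the other day 23 libraries to the 4 RAS libraries of days 8 to 14 outside the run. Empty vector libraries of the run differed from the others by −5.19 points (SD 1.65), the opposite of a pull in both arms. These 2 were also the shallowest of all libraries (4.49 and 3.5 tags per kb). A pull in RAS libraries alone is not covered by the test. On principal component 1 the day 23 libraries of the run lay at 46.47 and 46.93, further from the empty vector than the others at 9.54 and 2.25. By the same measure replicate 3 of day 23 was the odd one, at 61.24%, with the other 3 at 67.31 to 68.38%.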

How the results depend on the processing

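The series block, the runs without the separate run or without the 4 libraries named for another day, the empty vector of days 32 and 56 alone, RAS without day 18 or day 23 and the comparison of late list lengths were chosen after seeing the data. Of the alternative values, 304 stayed within the bounds of the reported one, 215 counts moved by more than 1.5 times, 3 kept their direction and no longer passed, and 2 reversed. Late RAS was closer to the empty vector than days 8 to 14, past the threshold, in every alternative run, with differences from 6.83 to 12.4 points. The late difference for early gains kept its direction in every alternative, from 19.9 points to 39.6 with every interval as deposited and 43.2 at a −log10 q of 5 or more. Ranking by fold, a summit inside the window and windows called in at least 4 libraries moved no count by over 1.5 times. The rule of 4 libraries could not change the counts of gained and lost windows. The filter on attainable p already leaves out windows called in fewer. Those unchanged counts are among the 304 values and show nothing about the processing. The tests of gene lists, with another distance, and of motifs, with the central part of the window, were not run. Without the separate run or without RAS day 23, days 18 to 23 were left with 2 RAS libraries, which allow no p under 0.0357 and 0.0222, so no value was made. The spread in depth, 3.5 to 29.32 tags per kb, limits what the shallowest lists can show, and list length where every interval is used.

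With every interval as deposited, gained and lost windows numbered 9908 and 668 for all RAS days, 12186 and 1893 for days 8 to 14 and 6864 and 832 for days 18 to 23. They were 513 and 4 for days 32 to 56 and 243 and 60 for late against early RAS. Windows in RAS only and in the empty vector only numbered 10559 and 1845 on day 8, 12961 and 1683 on day 32 and 14298 and 2172 on day 56, and those of the empty vector 864 only late and 65 only on day 8. The late difference for early losses reversed to 5.47 points (exact permutation p = 0.533). With a −log10 q of 5 or more, gained and lost windows numbered 9700 and 446 for all RAS days, 11004 and 1606 for days 8 to 14 and 6488 and 537 for days 18 to 23. They were 654 and 2 for days 32 to 56 and 256 and 34 for late against early RAS. Windows of 1 arm only numbered 9545 and 1547 on day 8, 11348 and 956 on day 32 and 13816 and 1342 on day 56, those of the empty vector 946 only late and 34 only on day 8, and the difference for losses reversed to 10.7 points (exact permutation p = 0.343). Both settings leave lists of unequal length, and lists were longer on average in RAS at matched ages. Lists of equal length in turn count a site as lost when stronger ones push it below the cut. The part that either plays was not tested apart.

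With lists of 37799 intervals, gained and lost windows numbered 1483 and 1359 for all RAS days, 3342 and 2193 for days 8 to 14 and 1916 and 1437 for days 18 to 23. They were 0 and 0 for days 32 to 56 and 35 and 45 for late against early RAS (787 and 774 at an unadjusted p under 0.05 by Fisher's exact test for days 32 to 56). Windows of 1 arm only numbered 3055 and 2185 on day 8, 1299 and 1195 on day 32 and 1385 and 1798 on day 56, and those of the empty vector 155 only late and 161 only on day 8. Fewer windows were tested by construction, and no other cause was tested. With no filter on attainable p, counts were 2363 and 2420 for all RAS days, 2485 and 1591 for days 8 to 14 and 866 and 552 for days 18 to 23. They were 0 and 0 for days 32 to 56 and 0 and 0 for late against early RAS (2343 and 2241 at an unadjusted p under 0.05 for days 32 to 56, 6917 and 6267 for late against early RAS), since all 136113 windows then enter the adjustment. An overlap with most of the window gave 74 gained windows at days 32 to 56 and 300 and 273 for late against early RAS, and the cause was not tested.

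Without the separate run, counts were 293 and 472 for all RAS days and 2953 and 2245 for days 8 to 14. They were 140 and 180 for days 32 to 56 and 171 and 199 for late against early RAS. The late differences were 20.57 points for early gains (exact permutation p = 0.143), −25.6 for early losses (p = 0.0714) and 5.08 in similarity to days 18 to 23 (p = 0.143), each with 2 libraries on one side, which against 6 allow no p under 0.0714. Without the libraries named for another day, counts were 1254 and 1249 for all RAS days, 2962 and 1844 for days 8 to 14 and 1253 and 850 for days 18 to 23. They were 161 and 126 for days 32 to 56 and 153 and 164 for late against early RAS. Without RAS day 18, days 18 to 23 gave 951 and 571. Against the empty vector of days 32 and 56 alone, days 32 to 56 gave 0 and 0 by Fisher's exact test with adjustment (266 and 366 at an unadjusted p under 0.05). All these leave fewer libraries, which raises the smallest p.

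With the replicate number as a block, counts were 2760 and 2926 for all RAS days, 2540 and 1760 for days 8 to 14 and 1630 and 1086 for days 18 to 23. They were 150 and 123 for days 32 to 56 and 235 and 198 for late against early RAS. With the series as a block they were 4048 and 4208 for all RAS days, 2591 and 1918 for days 8 to 14 and 1475 and 1052 for days 18 to 23. They were 140 and 180 for days 32 to 56 and 171 and 199 for late against early RAS. Replicate numbers were not taken to pair these samples, since 14 of 94 same-numbered pairs had a correlation of deviations over 0.1 (mean 0.035, against −0.018 in 184 other pairs) where every pair was required to. Of the 25 libraries, 17 correlated best with a library of their own number and 19 with one of their own series, a hint from the data and not the design; number and series partly coincide. The 120 gained and 94 lost windows of days 32 to 56 passed under both blocks, and no window that passed in the reported test passed in the other direction under either, in the 5 comparisons. For days 32 to 56 this tells little. Windows that separate the arms completely have the smallest p their margins allow under any block. The separate run, with no late RAS library, drops out of the series block there.

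Leaving out each library in turn gave 1520 to 4783 gained and 1465 to 5020 lost for all RAS days, 2536 to 3230 gained and 1637 to 2041 lost for days 8 to 14 and 3256 to 5130 gained and 2304 to 3548 lost for days 18 to 23. It gave 0 to 194 gained and 0 to 138 lost for days 32 to 56 and 100 to 932 gained and 98 to 883 lost for late against early RAS. It gave windows of RAS only and of the empty vector only of 5911 to 8167 and 5154 to 6536 on day 8, 5917 to 7643 and 5962 to 7166 on day 32 and 5071 to 9148 and 6757 to 8399 on day 56. For the empty vector it gave 439 to 870 windows only late and 333 to 665 only on day 8. Fewer libraries raise counts of complete separation by construction. The counts of 0 for days 32 to 56 arose without any 1 of its 6 RAS libraries, replicate 3 of empty vector day 8 or replicate 2 of empty vector day 32, with 1542 to 2093 gained and 1467 to 1862 lost at an unadjusted p under 0.05. The differences for early gains (19.9 to 28.3 points), early losses (−24.8 to −18.3), similarity and late list length kept their direction and their side of the threshold whichever library was left out. The list length of day 8 kept its direction. It could not pass, since even 3 against 4 libraries allow no exact permutation p under 0.0571.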

Other observations

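The tests over all chromosomes and of the 2 sides of chromosome 20 were chosen after the result was seen, as were the shares of lists per chromosome.

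Gains and losses of days 8 to 14 were spread unevenly over chromosomes. On chromosome 20, 205 of 970 tested windows were gained and 49 lost, and at days 18 to 23, 132 of 696 were gained and 40 lost. On chromosome 6 by contrast 361 of 2720 tested windows were gained and 355 lost at days 8 to 14. The share of the 75598 strongest intervals that lay on chromosome 20 was 2.58% ± 0.064 in RAS of days 8 to 14 (SD, n = 5) and 2.19% ± 0.06 in the empty vector (SD, n = 8). It was higher in 5 of 5 RAS libraries than in any empty vector library (two-sided exact permutation p = 0.00155, adjusted p = 0.00465). It was 2.51% ± 0.1 at days 18 to 23 (n = 6) and 2.33% ± 0.098 at days 32 to 56 (n = 6, exact permutation adjusted p = 0.004 and 0.0117). Between the empty vector and RAS of days 8 to 14 the share changed by 17.5% on chromosome 20, 11.9% on chromosome 18, 10.4% on chromosome 16 and −4.57% on chromosome 6 (exact permutation adjusted p = 0.00509 over 23 chromosomes for each).

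The third pattern weighed is this excess on chromosome 20. A small stretch of the chromosome is argued against, since gained windows exceeded lost ones on both sides of the widest stretch without windows (hg19, 26241759 to 29516314), 5.19 to 1 before it and 3.43 to 1 after it. More DNA of chromosome 20 in the RAS libraries may be the cause and stays open: relative to other chromosomes, the local background of weak intervals lay over the library's usual level 5.43 points more often in RAS of days 8 to 14 than in the empty vector, past the bound of 5 set beforehand. In a second calculation over all 23 chromosomes, with fewer intervals per library and relative to the median chromosome, the shift was the largest on chromosome 20 (5.98 points, exact permutation p = 0.00622, n = 5 and 8), yet its adjusted p was 0.143, and chromosome 16 gained 10.4% in share with a background shift of −0.02 points. By the first calculation the shift was 6.63 points at days 18 to 23 (exact permutation adjusted p = 0.0136, n = 6 and 8). At days 32 to 56, where the share of chromosome 20 was still higher, it was 1.86 points (exact permutation adjusted p = 0.216, n = 6 and 8). The background was recovered from the peak lists themselves, so it cannot tell more DNA from more accessible sites nearby. No biological explanation for the choice of chromosomes was tested.

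Windows that changed at days 8 to 14 lay near each other more often than windows drawn at random from those tested. Of gained windows 9.6% had another gained window within 10 kb, against 7.2% on average and 8.6% at most in 1000 draws. Of lost windows 11.9% had another lost window within 10 kb, against 5.3% on average and 7.0% at most. By this count the hypothesis set beforehand, that changes cluster beyond the layout of the tested windows, was met in both directions. A broad interval that reaches neighbouring windows calls them together, and the random draws did not allow for that. The part played by such intervals was not tested, so the excess does not show that separate sites cluster.

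In the empty vector, chance cannot be excluded for the 598 windows that parted day 8 from days 32 and 56, as 2 of 35 splits gave as many and the highest other gave 942. That split set the 3 libraries of one series and replicate 2 of day 56 against the rest, with mean backgrounds of 13.7 and 8.25 tags per kb. Splits with a larger contrast in depth gave fewer windows (276 at 15.63 against 6.32 tags per kb), and the part of the series was not tested. The series of the peak names held 2 or 3 empty vector libraries each, too few for a value within a series.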
